A study of Mus musculus with 22 samples.

How the data were processed

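Bulk RNA-seq was done on 22 primary tumours of the oral buccal mucosa of mice with floxed Trp53 and an inducible PIK3CA transgene, with or without floxed Keap1, and with or without benzo[a]pyrene (BAP) at initiation. Per the labels, frozen tumours were pulverised, total RNA was extracted with a column kit, and libraries were sequenced on an Illumina platform as paired-end reads. The deposited files give, for each library, an expected count and an effective length per Ensembl gene ID, made by the authors with RSEM per the file names. Each file lists 56748 gene IDs. The deposited expected count was a whole number for every gene in every file at a tolerance of 1e-09, and the deposited effective length, a length per gene in bases, was the same for a gene in all 22 files, so lengths were not used. Aligner, genome build, annotation and software versions are not given in the sources used here. Gene IDs were matched by ID to GENCODE M21 (GRCm38) for symbols and positions: 52073 IDs, holding 99.39% of all counts, had a symbol.

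Libraries were grouped by the genotype and treatment in the labels: 6 Keap1-wildtype untreated, 6 Keap1-wildtype BAP, 5 Keap1-deleted untreated and 5 Keap1-deleted BAP. Replicates are numbered in the order of deposition. No library was left out. Each pair of libraries was checked for duplication over 12352 genes with at least 10 counts in every library; the lowest chi-square per degree of freedom among 231 pairs was 96.5. Group assignment, comparisons, tests, gene lists, the rule for named genes and the first group of alternatives were fixed before the data were examined.

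Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 over the 4 groups, which left 19202 genes. Scaling was by TMM. All 22 libraries were fitted in a single quasi-likelihood model with robust dispersion and a term per group, and the quasi-likelihood F test was used for 5 contrasts: Keap1-deleted minus wildtype in untreated tumours, the same in BAP tumours, BAP minus untreated in each genotype, and the interaction, which is the Keap1 effect in BAP tumours minus that in untreated tumours. Adjusted p values of genes are Benjamini-Hochberg values of edgeR over all genes tested unless stated, with calls at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the edgeR statistics.

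A total of 32 gene lists covered NRF2 targets, other stress and metabolic programmes, keratinocyte states, immune programmes and markers of other cell types that a cheek tumour could hold. They name 530 genes, of which 490 were tested. Muc19, Adipoq, Ms4a1 and Ido1 are among those not tested, and 11 of the salivary gland markers were not. Some lists overlap: the pentose phosphate list shares G6pdx, Pgd, Tkt, Taldo1 and Me1 with the NRF2 list, so their results are not separate. Lists were tested by camera of limma 3.58.1 on log2 CPM (prior count 2) with the preset inter-gene correlation of 0.01, adjusted over 32 lists within a contrast, with the estimated correlation and fry as alternatives. List scores are the mean log2 CPM of the measured members per library, compared by two-sided exact permutation of the group labels, adjusted over 32 lists; the interaction has no such test. Counts described as adjusted over the list alone use Benjamini-Hochberg values of the edgeR p values of list members only.

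Named genes were taken by rule: Keap1, Nfe2l2, Trp53 and Pik3ca; per contrast, up to 8 genes per direction with the largest fold change among those passing with a mean of at least 1 CPM, leaving out predicted genes, pseudogenes and antigen receptor segments; up to 4 passing members of each called list, by smallest p, or the 2 smallest as values only; and Nqo1, Gclc, Gclm, Txnrd1, Srxn1, Slc7a11, Hmox1 and Gsta4 for Keap1 contrasts and Cyp1a1, Cyp1b1, Ahrr, Tiparp, Cdkn1a and Mdm2 for BAP contrasts. Krt5 and a few others outside the rule were chosen after their values were seen. Not all genes that the rule selects are reported here. For a gene with 0 counts in a group, the fold is a bound from a floor of 3 counts over that group. At these depths a floor of 3 counts over a group is 0.0148 to 0.0173 CPM.

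The first group of alternatives comprised DESeq2 size factors in edgeR, the DESeq2 1.42.0 test, limma-voom with sample quality weights, no low-count filter, a filter of at least 1 CPM in 5 libraries, only the groups compared in the fit, the R suffix of sample titles, the skeletal muscle score or the basal keratinocyte score as a covariate, and leaving out each library in turn. After the data were seen, others were added: leaving out Keap1-wildtype untreated 6, the library labelled Keap1-deleted BAP 2 and Keap1-deleted BAP 4 together, only titles not ending in R, the level of the Y-linked gene Ddx3y as a covariate, library totals as the only scaling, and list tests under some of these settings, with all lists also tested with each library left out in turn. For each comparison, 100 splits of its samples into groups of the same sizes, the real one included, were refitted; for the interaction, treatment labels were permuted within genotype. The pipeline was tested on simulated data with 50 changed genes per fold: in the 4 group comparisons it found 14% to 28% of 2-fold, 52% to 68% of 4-fold, 74% to 90% of 8-fold and 90% to 96% of 16-fold changes, with 3 to 6 false calls. It ranked a doubled NRF2 list first, with 1 or 2 other lists called as well. Some other lists share members with the NRF2 list. Genes were drawn independently, without the variation that genes share in the real libraries, so the number of false calls does not carry over to these data. Far fewer genes were changed than were called for the Keap1 effect in BAP tumours, so the shares found need not carry over either. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.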

Results

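RNA was sequenced from 22 primary mouse tumours of the cheek lining, a model of head and neck squamous cell carcinoma. Every tumour carried floxed Trp53 and a switchable activated PIK3CA transgene, both recombined by a tamoxifen-inducible Cre recombinase expressed from the Krt5 promoter of basal keratinocytes. Part of the tumours also carried floxed Keap1. KEAP1 is the ubiquitin ligase adaptor that marks NRF2, the transcription factor encoded by Nfe2l2, for degradation. Tumours were initiated with 4-hydroxytamoxifen alone, called untreated here, or together with benzo[a]pyrene (BAP), a carcinogen of tobacco smoke. The design gives 6 Keap1-wildtype untreated, 6 Keap1-wildtype BAP, 5 Keap1-deleted untreated and 5 Keap1-deleted BAP tumours. The stated purpose of the series is the part that KEAP1 and NRF2 play in radioresistance and in the immune microenvironment of such tumours. Total counts per library ranged from 29602879 to 38345425 in the Keap1-wildtype untreated group and from 30579115 to 36087574 in the Keap1-wildtype BAP group. They ranged from 32000650 to 39862777 in the Keap1-deleted untreated group and from 29235010 to 39784402 in the Keap1-deleted BAP group. Values below are CPM scaled by TMM, a trimmed-mean normalisation, or log2 fold changes with their standard error (SE) from edgeR. Sex and age of the animals, and whether each tumour came from its own animal, are not stated.

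Keap1 (ENSMUSG00000003308, chromosome 9, 21229730 to 21239361, minus strand in GENCODE M21 on GRCm38) was measured in all libraries. Its mean was 57.1 ± 12.1 CPM (SD, n = 6) in Keap1-wildtype untreated tumours, 58.1 ± 4.22 CPM (SD, n = 6) in Keap1-wildtype BAP tumours, 28.9 ± 5.96 CPM (SD, n = 5) in Keap1-deleted untreated tumours and 30.4 ± 21.9 CPM (SD, n = 5) in Keap1-deleted BAP tumours. The library labelled Keap1-deleted BAP 2 held 65.6 CPM, within the wildtype range, while the other 4 libraries of that group held 29.8, 9.45, 32.2 and 15.0 CPM. The log2 fold change of Keap1 with deletion was -0.98 (SE 0.32, edgeR adjusted p = 0.137, unadjusted p = 0.00586) in untreated tumours and -0.93 (SE 0.32, adjusted p = 0.0253) in BAP tumours. The call in BAP tumours was lost without Keap1-deleted BAP 3 (-0.70) or 5 (-0.76, adjusted p = 0.0707) and with library totals as the only scaling (adjusted p = 0.235). It was also lost with the basal keratinocyte score as a covariate, under which 0 genes were called in BAP tumours. These are gene-level counts, which take in exons outside any deleted part. Nfe2l2 (ENSMUSG00000015839, chromosome 2, 75675513 to 75704641, minus strand) averaged 184 ± 72.2, 288 ± 117, 139 ± 48.1 and 86.8 ± 6.05 CPM (SD) in the same order of groups. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873, plus strand) averaged 13.4, 10.1, 21.1 and 36.6 CPM, with 110 CPM in Keap1-deleted BAP 3. Pik3ca (ENSMUSG00000027665, chromosome 3, 32397671 to 32468486, plus strand) averaged 106, 99.7, 102 and 89.1 CPM and was not called in any of the 5 comparisons. The files give no separate count for the PIK3CA transgene.

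**Figure D1:**
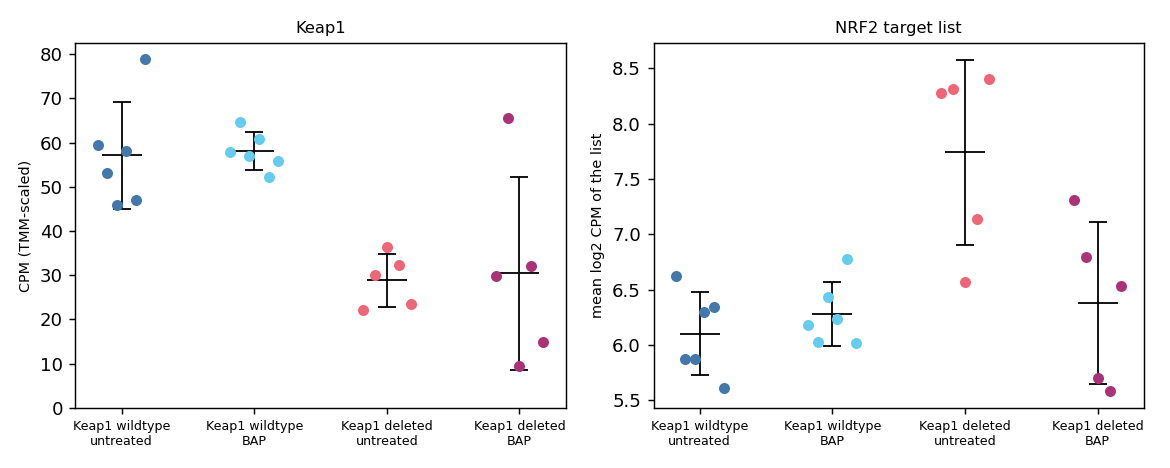
Each point is 1 library. The left panel shows TMM-scaled CPM of Keap1 and the right panel the mean log2 CPM over 35 NRF2 target genes, by group, with bars for the group mean ± SD. The library labelled Keap1-deleted BAP 2 lies at 65.6 CPM of Keap1, and the NRF2 target score averages 7.74 in Keap1-deleted untreated tumours against 6.10, 6.28 and 6.38 in the other groups.

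The first principal component held 45.88% of the variance and the second 9.61%. All 5 Keap1-deleted BAP libraries lay between 125 and 189 on the first component, and all 6 Keap1-wildtype BAP libraries between -132 and -92.1. Keap1-wildtype untreated 6 lay at 162, while the other 5 libraries of its group lay between -141 and -15.1. Keap1-deleted untreated 3 and 4 lay at 129 and 116, and the other 3 libraries of their group between -28.6 and 42.1. Keap1-wildtype untreated 6 also had the lowest basal keratinocyte score of its group, 4.95 mean log2 CPM against a group mean of 7.51 ± 1.30 (SD, n = 6).

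**Figure D2:**
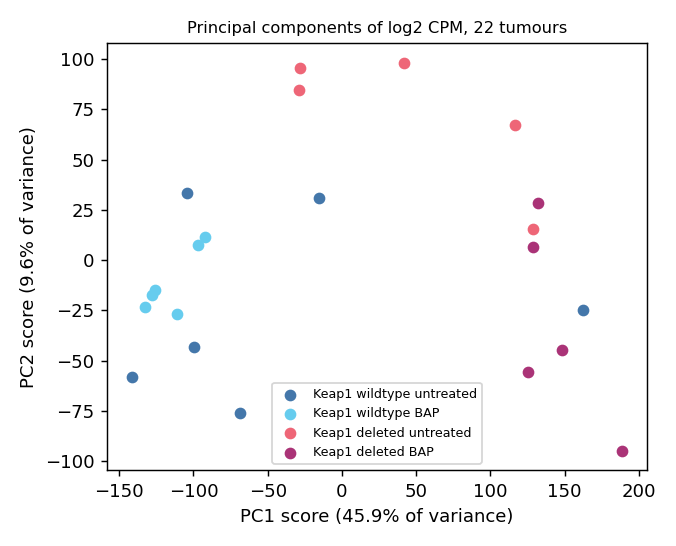
Each point is 1 library on the first (45.88% of the variance) and second (9.61%) principal components of log2 CPM, coloured by group. Keap1-wildtype untreated 6 lies at 162 on the first component, among the Keap1-deleted BAP libraries.

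The first comparison asked what Keap1 deletion changed in tumours initiated without BAP. Genes of the NRF2 antioxidant programme were higher in the Keap1-deleted tumours: of 35 measured NRF2 targets 6 rose, 0 fell and the rest did not pass, and 27 rose when adjusted over the list alone. Gstm1, a glutathione transferase, rose by 3.50 (SE 0.57, adjusted p = 0.00756), and Blvrb, biliverdin reductase B, by 2.65 (SE 0.40, adjusted p = 0.00424). Gstp1 rose by 1.71 (SE 0.32, adjusted p = 0.0235), and Txnrd1, thioredoxin reductase, by 1.87 (SE 0.35, adjusted p = 0.0238). Nqo1, a quinone reductase, had 317 ± 143 CPM (SD, n = 5) in deleted and 49.8 ± 24.7 CPM (SD, n = 6) in wildtype tumours, a log2 fold change of 2.67 (SE 0.56, adjusted p = 0.0457). Not passing were Gclc at 2.45, Slc7a11, the cystine importer, at 2.78, Srxn1 at 1.86, Gclm at 1.45 and Gsta4 at 1.29, with adjusted p from 0.0739 to 0.353, and Hmox1 at 0.06. The mean log2 CPM of the list was higher by 1.64 in deleted tumours (two-sided exact permutation p = 0.00433, adjusted p = 0.0519 over 32 lists). Camera with its preset correlation gave the list an adjusted p of 3.82e-17, and with an estimated correlation the adjusted p was 0.354.

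Across all genes 41 rose and 15 fell in the untreated comparison, at an adjusted p under 0.05 by edgeR, and 3382 had an unadjusted p under 0.05. The largest increases included Adam23 at 5.42 (SE 0.82), Nrxn2, a neurexin, at 4.84, Gldc, glycine decarboxylase, at 3.99, Mmp12, macrophage elastase, at 3.49, Serpine2, a secreted protease inhibitor, at 3.11 and Enpp2, which encodes autotaxin, at 2.97. Inmt was at least 110-fold higher, with 0 counts in the wildtype libraries and 1 CPM or more in 3 of 5 deleted ones. Igha, the constant region of immunoglobulin A, rose by 5.96 (SE 1.01, adjusted p = 0.00972). The genes that fell most were the mitochondrial cysteine tRNA mt-Tc at -3.02, the noncoding RNA Zfas1 at -1.51, the meiotic recombination gene Mnd1 at -1.49, Miip at -1.40, the DNA repair gene Brca2 at -1.39, Ang at -1.33, Mrgbp at -1.29 and the nucleoside transporter Slc29a2 at -1.11. Inmt, Adam23, Gstm1, Serpine2, Blvrb and Igha passed with each of the 11 libraries left out in turn, while the other called genes named here, Nqo1, Txnrd1 and Gstp1 among them, each failed without at least 1 library. Leaving out Keap1-wildtype untreated 6 took the number of calls to 2731, and leaving out wildtype untreated 2, 3 or 4 or deleted untreated 1, 2, 4 or 5 took it to between 16 and 28. With only the 11 libraries of this comparison in the fit, edgeR made 0 calls with 2379 genes at an unadjusted p under 0.05, while over all 22 libraries DESeq2 made 915 calls, of which 45.1% were higher, and limma-voom with sample weights 3431, of which 62.5% were higher.

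Lists of stromal and immune cell types had higher scores in Keap1-deleted untreated tumours, but few of their members passed. Camera with a preset correlation called 18 of 32 lists, and 0 of these with an estimated correlation, and the smallest exact permutation p of a score after adjustment over 32 lists was 0.0519. The skeletal muscle score differed by 2.73, the fibroblast and matrix score by 1.95, the macrophage and monocyte score by 1.69 and the endothelium score by 1.33, each with 0 members rising or falling and an estimated-correlation adjusted p of 0.403. Adjusted over the list alone, 8 of 14 endothelial genes rose, 2 of 18 muscle genes rose, and 0 fibroblast and 0 macrophage genes passed. In the B and plasma cell list, with a score difference of 2.74, Igha rose (1 of 11, 4 adjusted over the list alone), with an estimated-correlation adjusted p of 0.399. The glycolysis and hypoxia score differed by -0.79 and the proliferation score by -0.38, with 0 members passing over all genes, 7 and 6 falling when adjusted over the list alone, and an adjusted p of 0.403 with an estimated correlation for both. In the aryl hydrocarbon receptor list, which shares Nqo1 and Aldh3a1 with the NRF2 list, 1 of 11 rose. Adjusted over the list alone 2 rose and 1 fell, and the adjusted p was 0.354 with an estimated correlation. Scores of the remaining called lists differed by 1.49 for neutrophils, 1.46 for mast cells and eosinophils, 1.37 for partial epithelial-mesenchymal transition, 1.49 for adipocytes, 1.47 for nerve and Schwann cells, 0.43 for the pentose phosphate pathway, -0.23 for DNA damage repair, -0.69 for basal keratinocyte and -0.52 for type I interferon genes, with estimated-correlation adjusted p from 0.403 to 0.815. Of their members Brca2 fell and no other passed, and adjusted over the list alone 4 pentose phosphate, 3 nerve, 1 neutrophil and 1 adipocyte gene rose, and Brca2 and 1 adipocyte gene fell. The basal keratinocyte call was lost without Keap1-wildtype untreated 1 or 2 or Keap1-deleted untreated 3 or 4 (differences from -0.59 to -0.34), while without Keap1-wildtype untreated 6 the difference was -1.21 (adjusted p = 0.00240). The pentose phosphate list was called in 5 of the 11 fits that left out 1 library, and the interferon call was lost without Keap1-wildtype untreated 5 or 6 or Keap1-deleted untreated 1 or 5, with a difference of 0.08 without Keap1-wildtype untreated 6.

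The second comparison asked what Keap1 deletion changed in tumours initiated with BAP. Keratinocyte genes fell and fibroblast, macrophage and muscle genes rose in the Keap1-deleted tumours. Of 14 basal keratinocyte genes 13 fell, over all genes and adjusted over the list alone: Trp63, the master regulator of squamous epithelium, at -4.85 (SE 0.77, adjusted p = 3.32e-04), Lamb3 at -4.70, Cdh3 at -4.09 and Itgb4 at -3.45. Krt5 averaged 192 CPM in deleted against 7052 CPM in wildtype BAP tumours, and Krt14 702 against 34576 CPM. Of 20 differentiation genes 19 fell, also when adjusted over the list alone, among them the cornified envelope genes Sprr3 at -8.67 (SE 1.62), Sprr1a at -6.74 and Krtdap at -5.37 and the crosslinking enzyme Tgm1 at -5.36. Of 13 stress keratins and alarmins 11 fell and 0 rose (12 adjusted over the list alone), including Krt6a at -6.14, Krt16 at -6.18, Krt6b at -6.48 and Sprr2d at -7.16. The mean scores of these 3 lists differed by -4.08, -6.85 and -5.68 (exact permutation p = 0.00216 each, the smallest the exact test can give for 5 against 6 tumours, adjusted p = 0.00630 over 32 lists). Camera adjusted p values were 5.51e-08, 6.38e-09 and 2.23e-06 with the preset correlation and 0.493 for each with an estimated correlation.

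All 18 fibroblast and matrix genes rose in Keap1-deleted BAP tumours, over all genes and adjusted over the list alone. Pdgfra, a receptor for platelet-derived growth factor, rose by 6.01 (SE 1.0, adjusted p = 3.73e-04), the collagen crosslinking enzyme Lox by 6.45, decorin (Dcn) by 6.21 and Pdgfrb by 3.05. Of 20 macrophage and monocyte genes 17 rose and 1 fell (18 and 1 adjusted over the list alone), with the mannose receptor Mrc1 at 7.11 (SE 1.19), Ms4a7 at 5.15, Adgre1, which encodes the F4/80 antigen, at 5.06 and the complement gene C1qc at 4.82. Of 18 skeletal muscle genes 15 rose (15 adjusted over the list alone), such as the myosin genes Myh2 at 7.67, Myl1 at 6.90 and Mylpf at 3.94 and the nebulin gene Neb at 4.28. Scores differed by 3.91, 3.60 and 4.41 (exact permutation p = 0.00216, 0.00216 and 0.0130, adjusted p at most 0.0260), and the estimated-correlation adjusted p was 0.493, 0.493 and 0.612. Of 20 genes of partial epithelial-mesenchymal transition 11 rose and 2 fell (the same counts adjusted over the list alone), with the transcription factors Zeb2 at 4.03, Zeb1 at 4.08 and Snai1 at 5.19 and the integrin Itga5 at 2.90 (estimated-correlation adjusted p = 0.668). The score difference of that list was 1.97, or -0.15 (camera adjusted p = 0.806) with the basal keratinocyte score as a covariate.

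**Figure D3:**
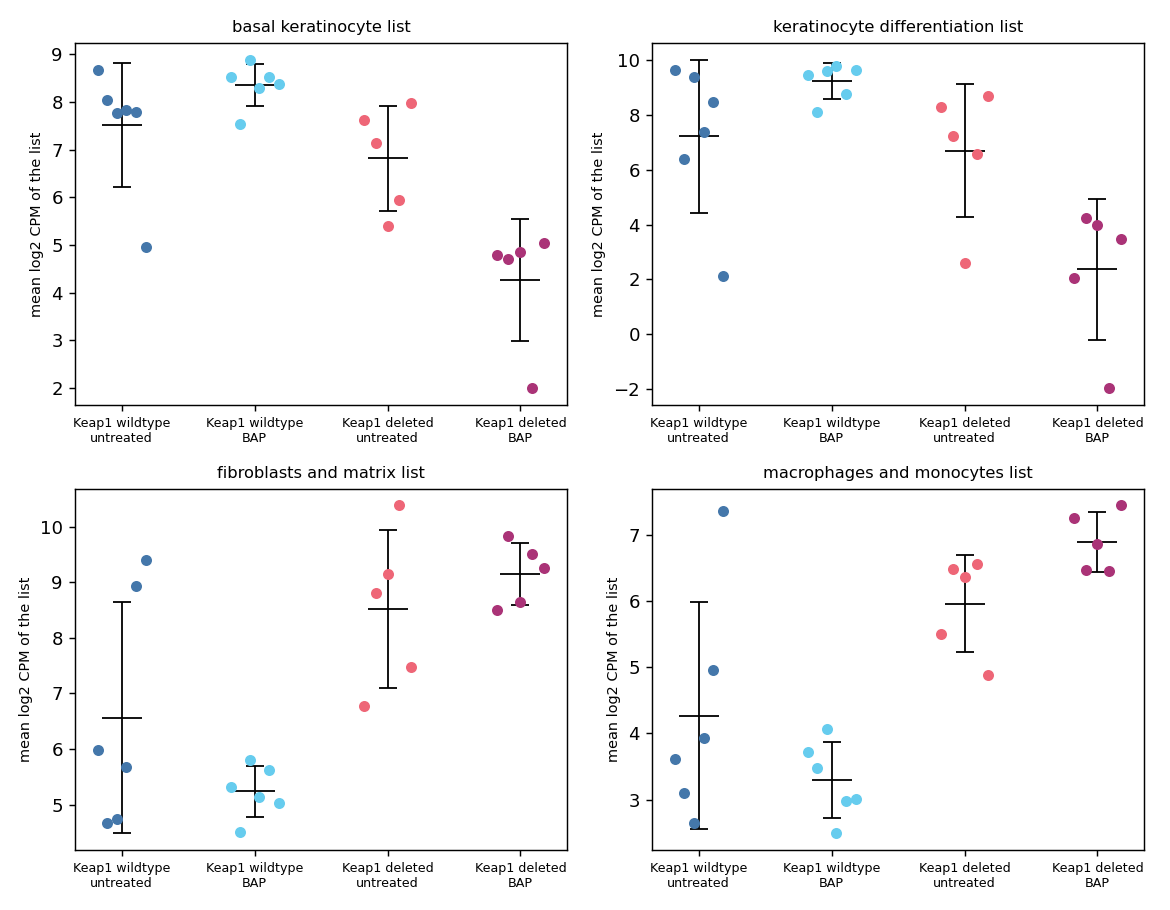
Each point is 1 library and each panel the mean log2 CPM of 1 list of marker genes, by group, with bars for the group mean ± SD. Basal keratinocyte and differentiation scores average 4.27 and 2.36 in Keap1-deleted BAP tumours against 8.35 and 9.22 in Keap1-wildtype BAP tumours, while fibroblast and macrophage scores average 9.15 and 6.89 against 5.24 and 3.29.

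Immune lists other than macrophages moved less evenly in the BAP tumours. Of 23 type I interferon response genes 15 rose and 0 fell (19 adjusted over the list alone), including Ddx58 at 2.22, Ifit2 at 3.0, Oas2 at 2.73 and Ifit3 at 4.77. Of 14 genes of cytotoxic lymphocytes and natural killer (NK) cells 10 rose (14 adjusted over the list alone), among them Klrk1 at 3.08 and Nkg7 at 4.79, while Ncr1 and Klre1 reached 1 CPM in 1 of 5 deleted libraries. Of 15 genes of major histocompatibility complex (MHC) class II and dendritic cells 6 rose (6 adjusted over the list alone), with Batf3 at 2.82, Zbtb46 at 2.41, Flt3 at 2.33 and H2-DMa at 2.0. Of 11 mast cell and eosinophil genes 6 rose (7 adjusted over the list alone), with Kit at 1.64, Tpsb2 at 3.19, Fcer1a at 3.68 and Siglecf at 3.63. Of 14 endothelial genes 3 rose (2 adjusted over the list alone), which were Tek at 1.35 and the lymphatic genes Lyve1 at 4.97 and Prox1 at 2.85. The estimated-correlation adjusted p was 0.753 for interferon, 0.612 for NK, 0.697 for MHC class II, 0.612 for mast and 0.732 for endothelial genes. Without Keap1-deleted BAP 1 the interferon score difference was 0.90 against 1.61 and its preset-correlation adjusted p was 0.134, and the calls of Ifit3 (2.16), Oas2 (1.38) and Klrk1 (2.09) were lost. With 1 library left out the MHC class II list was called in 10 of 11 fits (lowest difference 0.78, without Keap1-deleted BAP 3), the mast cell list in 9 and the endothelium list in 7. Flt3 (1.55) and Tpsb2 (2.55) were not called without Keap1-deleted BAP 3, and Prox1 and Fcer1a failed in 8 and 5 of the 11 fits that left out 1 library. Lists not called by camera were T cells (score difference 0.54; 2 rose, 1 fell), regulatory T cells and checkpoints (0.37; 1 rose, 3 fell), B and plasma cells (1.76; 5 rose, 1 fell), neutrophils (0.13; 3 rose, 2 fell), myeloid chemoattractants (0.29; 5 rose, 3 fell) and interferon gamma and antigen presentation (0.56; 5 rose, 4 fell), with camera adjusted p from 0.307 to 0.746 by the preset and from 0.754 to 0.925 by an estimated correlation. By exact permutation the B and plasma cell score did pass (p = 0.0108, adjusted p = 0.0231 over 32 lists). Adjusted over the list alone these counts differed by at most 1.

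Genes of glycolysis and of sterol synthesis fell in Keap1-deleted BAP tumours, and oxidative phosphorylation genes in part. Of 18 glycolysis and hypoxia genes 17 fell (17 adjusted over the list alone), among them Pfkp at -2.77 (SE 0.41, adjusted p = 2.72e-04), lactate dehydrogenase A (Ldha) at -1.90, Ndrg1 at -3.10 and hexokinase 2 (Hk2) at -3.17. Of 16 genes of PI3K-mTOR growth and sterol synthesis 14 fell (14 adjusted over the list alone), such as the sterol regulator Srebf2 at -1.49, Hmgcs1 at -2.17 and Sqle at -2.09. Of 18 oxidative phosphorylation genes 8 fell and 1 rose (8 and 1 adjusted over the list alone), with Uqcrc1 at -1.13, Ndufs1 at -1.06, Uqcrc2 at -0.95 and Uqcrfs1 at -0.87. Score differences were -2.06, -1.45 and -0.52 (exact permutation p = 0.00216, 0.00216 and 0.00433, adjusted p at most 0.0115), and the estimated-correlation adjusted p was 0.493, 0.493 and 0.668. With the basal keratinocyte score as a covariate they were -0.77, -0.24 and -0.17 (camera adjusted p = 1.58e-04, 0.0740 and 0.0740).

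NRF2 targets went both ways in the BAP tumours: 13 of 35 rose and 5 fell (14 and 6 adjusted over the list alone). Txnrd1 rose by 2.30 (SE 0.35, adjusted p = 3.20e-04), Nqo1 by 1.54 (SE 0.54, adjusted p = 0.0293) and Gclm by 1.30, while Hmox1, heme oxygenase 1, fell by 1.44 on the log2 scale. Nqo1 failed in 4 of the 11 fits that left out 1 library, with 0.83 (adjusted p = 0.204) without Keap1-deleted BAP 1, and Gclm failed without Keap1-deleted BAP 1 (0.93) or Keap1-wildtype BAP 1 (1.21). Slc7a11 at -1.51, Gsta4 at -1.61, Gclc at 0.37 and Srxn1 at 0.26 did not pass. The mean score of the list differed by 0.10 (exact permutation p = 0.760), with a camera adjusted p of 0.411 by the preset and 0.925 by an estimated correlation. Nfe2l2 itself fell by 1.73 on the log2 scale (SE 0.33, adjusted p = 7.14e-04). Trp53 rose by 1.85 (SE 0.47, adjusted p = 0.00420), or by 0.84 without Keap1-deleted BAP 3.

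Of 19202 genes tested in the BAP comparison 3900 rose and 3846 fell by edgeR, 40.3% of all genes, while with library totals as the only scaling 73.4% of 8244 calls were higher. The macrophage receptor Vsig4 was at least 578-fold higher, the glutamate receptor genes Gria4 and Grik2 at least 555-fold and 436-fold, and Rspo2, a Wnt pathway agonist, at least 376-fold. Agtr2, at least 769-fold higher, and Cacng2, at least 671-fold higher, drew 72.2% and 93.4% of their group total from 1 library. Prl2c2, of the prolactin family, rose by 10.46. In the other direction Chil4, a chitinase-like protein, was at least 16200-fold lower, with 68.3% of the wildtype total in 1 library, Tex19.1 at least 254-fold, with 53.4% in 1 library, and Mir7678 at least 139-fold lower. Sprr2a2 at -12.13, Sprr2a1 at -10.94, Krt4 at -9.64, Sprr3 at -8.67 and Sprr2a3 at -8.64 fell the most of the other named genes, and the Sprr2a paralogs are similar enough in sequence to share reads. A floor of 3 counts over a group stands behind each "at least", and such floors cover counting error only.

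In the lists not yet named, 9 of 20 p53 targets fell and 6 rose in Keap1-deleted BAP tumours (score difference -0.44), 7 of 22 proliferation genes fell (-0.23), and 3 of 20 DNA repair genes fell and 1 rose (-0.12). In the pentose phosphate list 3 of 11 fell and 2 rose (-0.28), and among aryl hydrocarbon receptor targets 3 of 11 rose and 2 fell (0.46). Of 8 genes of simple and glandular epithelium 3 fell (-2.13), of 11 nerve and Schwann cell genes 4 rose and 2 fell (1.34), and of 5 erythrocyte genes 0 passed (-2.52). Salivary gland genes (2 rose and 1 fell of 7, -0.63) and adipocyte genes (2 rose and 3 fell of 10, -0.31) had a median fold change, a mean and a test that differed in sign. Camera called none of these 10 lists at the preset correlation, with adjusted p from 0.121 to 0.953, or from 0.668 to 0.972 with an estimated correlation, and adjusted over the list alone the counts differed by at most 1. Exact permutation of the scores, adjusted over 32 lists, did call p53 targets (adjusted p = 0.00630), nerve and Schwann cells (0.0160), simple epithelium (0.0198) and erythrocytes (0.0485). Of the 41 genes higher with deletion in untreated tumours, 26 were also higher in BAP tumours against 8.33 expected by chance (Fisher's exact p = 2.33e-09), and of the 15 lower genes 5 were shared against 3 expected (Fisher's exact p = 0.165). These comparisons share no library, but both come from the same fit. With only its own libraries in the fit, the untreated comparison made 0 calls. Fisher's test treats genes as independent although they vary together, so its p values do not measure the spread between tumours. The number of calls fell to 3133 with the skeletal muscle score as a covariate and to 0 with the basal keratinocyte score as a covariate (1084 genes at an unadjusted p under 0.05), a score whose values in the 2 BAP groups do not overlap. Numbers in the sample titles do not overlap between these 2 groups.

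The third comparison asked how Keap1-wildtype tumours initiated with BAP differed from untreated ones. Interferon, fibroblast and macrophage genes had lower values and keratinocyte genes higher values with BAP, but no single gene passed by edgeR. Named members, all without a call, were Ifit3 at -4.79 (SE 1.38) and Oas2 at -2.75 in the interferon list, Fap at -4.38 and Dcn at -3.73 in the fibroblast list, and Fcgr1 at -3.71 and C1qa at -3.27 in the macrophage list, with edgeR adjusted p from 0.145 to 0.149. Cyp1a1 and Cyp1b1, the cytochromes that respond to polycyclic hydrocarbons through the aryl hydrocarbon receptor, were at 0.89 (SE 1.21, adjusted p = 0.796) and -3.51 (SE 0.84, adjusted p = 0.145), and Ahrr, Tiparp, Cdkn1a and Mdm2 were at 0.74, 0.59, 0.85 and -0.19. Nfe2l2 was at 0.65 (adjusted p = 0.353), Trp53 at -0.40 and Keap1 at 0.02.

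By edgeR 0 genes passed in that comparison and 2622 had an unadjusted p under 0.05, while DESeq2 called 902 genes and limma-voom 0. Camera called 18 of 32 lists with a preset correlation and 0 with an estimated one, and the smallest adjusted exact permutation p of a score was 0.0693. The interferon score differed by -1.54 (0 passed over all genes, 21 of 23 fell adjusted over the list alone), the fibroblast score by -1.33 (0 and 16 of 18), the macrophage score by -0.98 (0 and 13 of 20), the muscle score by -2.13 (0 and 9 of 18), the NK score by -1.17 (0 and 9 of 14) and the MHC class II score by -1.04 (0 and 2 of 15). The differentiation score differed by 2.0, the basal keratinocyte score by 0.84, the glycolysis score by 0.83 and the PI3K-mTOR score by 0.55, with 0 members passing either way of adjustment. The adjusted p with an estimated correlation was 0.469 for each of these 10 lists. The other 8 called lists were stress keratins and alarmins (1.10), erythrocytes (1.67), the pentose phosphate pathway (0.24), proliferation (0.15), oxidative phosphorylation (0.16), T cells (-0.69), regulatory T cells and checkpoints (-0.50) and interferon gamma and antigen presentation (-0.77), with estimated-correlation adjusted p of 0.469 or 0.6253. Adjusted over the list alone 5 interferon gamma and 1 regulatory T cell genes fell, and 0 members of the other 6 passed. The aryl hydrocarbon receptor list was not called (score difference -0.02, camera adjusted p = 0.662), and its median, mean and test differed in sign, as they did for p53 targets and DNA repair. Without Keap1-wildtype untreated 6 the macrophage difference was -0.36 and its preset-correlation adjusted p 0.0944, the fibroblast difference -0.76, the interferon difference -0.93, the basal keratinocyte difference 0.33 with an adjusted p of 0.125, and the differentiation difference 0.97 and that of stress keratins and alarmins 0.46 with an adjusted p of 0.263. Not called without that library were also NK (-0.66, adjusted p = 0.123), T cell (-0.49), regulatory T cell (-0.32) and interferon gamma genes (-0.42). The camera call of stress keratins and alarmins was also lost without Keap1-wildtype untreated 2 (0.91, adjusted p = 0.0515) or Keap1-wildtype BAP 6 (0.94, adjusted p = 0.0726). Of the 12 fits that left out 1 library, 7 called the pentose phosphate, oxidative phosphorylation and regulatory T cell lists each and 8 the proliferation list. Title numbers do not overlap between these groups and titles end in R in 4 of 6 untreated and 1 of 6 BAP tumours; with that suffix as a covariate edgeR called 37 genes, and among titles without it 474.

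The fourth comparison asked how Keap1-deleted tumours initiated with BAP differed from untreated ones. Many keratinocyte genes and a part of the NRF2 target genes fell with BAP. Of 20 differentiation genes 11 fell (18 adjusted over the list alone), among them Krt13 at -7.95 (SE 1.80, adjusted p = 0.0202), Sprr3 at -7.46, Krt76 at -4.93 and Tgm1 at -4.69. Of 13 stress keratins and alarmins 9 fell (12 adjusted over the list alone), with Sprr2d at -5.94, Krt6a at -4.68, the alarmin Il1a at -4.56 and Krt17 at -4.50, and of 14 basal keratinocyte genes 8 fell (10 adjusted over the list alone), with Krt14 at -4.05, Lamb3 at -3.67, Trp63 at -3.49 and Itgb4 at -2.73. Of 35 NRF2 targets 11 fell and 0 rose (18 adjusted over the list alone), with Slc7a11 from 612 to 41.7 CPM (-3.88, SE 0.78, adjusted p = 0.0155), Gstm1 at -2.44, Abcc4 at -1.73 and Taldo1 at -1.54. Score differences were -4.32, -4.55, -2.54 and -1.36 (exact permutation p = 0.0317, 0.0238, 0.00794 and 0.0476, or 0.113, 0.113, 0.102 and 0.127 adjusted over 32 lists, so that no score passed), and the estimated-correlation adjusted p was 0.469 for each. The 0.00794 of the basal keratinocyte score is the smallest p the exact test can give for 5 against 5 tumours.

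Other gene groups fell in part in Keap1-deleted tumours with BAP. Of 16 PI3K-mTOR and sterol genes 5 fell (11 adjusted over the list alone), including Idi1 at -2.23, Hmgcs1 at -1.65 and Fdft1 at -1.40. Of 11 B and plasma cell genes 3 fell (3 adjusted over the list alone), which were Igha at -3.48, Blk at -2.52 and Sdc1, a syndecan that epithelial cells also express, at -1.94. Of 17 T cell genes Cd5 (-2.41) and Il7r (-1.71) fell (2 also adjusted over the list alone), of 16 neutrophil genes Acod1 (-2.92) fell (5 adjusted over the list alone), of 8 simple epithelial genes Elf3 (-5.09) and Cldn4 (-3.98) fell (3 adjusted over the list alone), and of 11 pentose phosphate genes Taldo1 and G6pdx (-1.43) fell (4 fell and 1 rose adjusted over the list alone). Among macrophage genes Cd163 rose by 2.52, and among proliferation genes Cdk1 rose by 0.76, each 1 gene of its list by either adjustment. The estimated-correlation adjusted p of these 8 lists was 0.469 or 0.498. In adipocyte (-1.67), NK (1.12), endothelium (-0.65), fibroblast (0.63) and interferon (0.60) lists 0 members passed, 1 adipocyte gene fell adjusted over the list alone, and the estimated-correlation adjusted p ran from 0.469 to 0.730. The NK call was lost without Keap1-deleted BAP 1 (0.53, adjusted p = 0.0930). Of the 10 fits that left out 1 library, 4 called the pentose phosphate list, 5 endothelium, 6 T cells, 7 simple epithelium and 8 B and plasma cells. The interferon call was lost without Keap1-deleted untreated 1 (0.40) or 5 (0.31) or Keap1-deleted BAP 1 (-0.12), and the fibroblast call without Keap1-deleted untreated 1 (0.19) or 5 (0.38) or Keap1-deleted BAP 2 (0.45) or 4 (0.54).

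Of the single genes in that comparison, 181 rose and 991 fell by edgeR. Defb4, a beta-defensin, was at -7.74, Krt42 at -7.59, Sprr2a2 at -7.44 and Sprr2i at -6.73, while the casein gene Csn1s1 was at least 286-fold lower, with 76.1% of the untreated total in 1 library, and Mir7678 at least 112-fold. Msln, mesothelin, rose by 3.86. Genes typical of salivary glands, amylase 1 (Amy1) at 6.76, Car6 at 5.83 and Dnase1 at 3.63, were called with all libraries but not without Keap1-deleted BAP 1 (2.04, 1.67 and 1.74). Cfap300 at 3.89 and Cep126 at 3.78 were not called without Keap1-deleted BAP 5 (1.01 and 0.86), and Cacng2 at 8.57 and Adcy8 at 7.54 reached 1 CPM in 2 of 5 BAP tumours. Cdkn1a, which encodes the cell cycle inhibitor p21, fell by 1.98 on the log2 scale (adjusted p = 0.0243), while Cyp1a1 at -1.0, Cyp1b1 at -1.10, Ahrr at 0.58, Tiparp at 0.78, Mdm2 at 0.35, Nfe2l2 at -0.68 (adjusted p = 0.262), Trp53 at 0.79 and Keap1 at 0.07 did not pass. Leaving out 1 library took the number of calls to 181 or 504 without Keap1-deleted untreated 1 or 2, to 187 without Keap1-deleted untreated 5, and to 394, 219 or 361 without Keap1-deleted BAP 1, 4 or 5. Slc7a11, Trp63, Tgm1, Sprr3, Defb4, Elf3 and Sdc1 passed with each of the 10 libraries left out, and the other called genes named here each failed without at least 1. The total was 352 with only these libraries in the fit, 2063 by DESeq2, 3791 by limma-voom, 398 without the low-count filter and 2 with the basal keratinocyte covariate.

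The fifth comparison, the interaction, asked whether the Keap1 effect differed between BAP and untreated tumours. The Keap1 effect on a part of the NRF2 targets and keratinocyte genes was lower with BAP, and that on a part of the macrophage and interferon genes higher. Of 35 NRF2 targets 7 had a lower effect and 0 a higher one (14 and 0 adjusted over the list alone), with Slc7a11 at -4.28 (SE 0.98, adjusted p = 0.0296), Gsta2 at -5.08, Abcc4 at -2.04 and G6pdx at -1.94. Of 20 macrophage genes 9 had a higher effect (13 higher and 1 lower adjusted over the list alone), with Mrc1 at 6.32, Fcgr1 at 5.42, C1qa at 5.07 and C1qc at 4.84, and of 23 interferon genes 4 had a higher effect (21 adjusted over the list alone), with Irf7 at 5.90, Oas2 at 4.39, Zbp1 at 4.31 and Stat2 at 2.42. The estimated-correlation adjusted p was 0.538, 0.538 and 0.562 for these lists. Of 20 differentiation genes 11 had a lower effect, of 13 stress keratins and alarmins 8 and of 14 basal keratinocyte genes 7 (16, 12 and 11 adjusted over the list alone), with Sprr3 at -8.28, Krt6a at -5.56 and Trp63 at -4.07 and an estimated-correlation adjusted p of 0.538 for each. In total 475 genes had a higher and 858 a lower Keap1 effect with BAP by edgeR, with 5082 at an unadjusted p under 0.05. That balance turned with library totals as the only scaling, where 62.2% of 1772 calls were higher, and among titles not ending in R, where 53.1% of 680 were. Nfe2l2 at -1.33 (adjusted p = 0.0712), Trp53 at 1.19 (adjusted p = 0.250) and Keap1 at 0.05 (adjusted p = 0.956) did not pass. Leaving out Keap1-deleted untreated 1, 2 or 5 took the total of 1333 calls to 1 and leaving out Keap1-deleted BAP 4 took it to 2, and Slc7a11 then had an adjusted p of at most 0.0700. It was 512 or 349 without Keap1-deleted BAP 1 or 5, 629 or 2309 without Keap1-wildtype untreated 5 or 1, and between 501 and 800 without Keap1-wildtype BAP 1, 3, 4, 5 or 6. The total was 2914 by DESeq2, 111 without the low-count filter and 0 with the basal keratinocyte covariate (1329 genes at an unadjusted p under 0.05).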

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

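The tests of explanations, the splits of the samples and the search for outlying libraries below were specified after results had been seen, while the interaction tests of genes and lists were specified earlier.

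With all libraries in the fit, the interaction test called 1333 genes whose Keap1 effect differed between BAP and untreated tumours. The total was 0 with the basal keratinocyte score as a covariate, and leaving out single Keap1-deleted libraries took it to as few as 1. Across 13 lists, score differences of the interaction were -1.53 for NRF2 targets, -0.71 for the pentose phosphate pathway, -3.39 for basal keratinocyte, -6.32 for keratinocyte differentiation, -5.65 for stress keratins and alarmins, -1.46 for PI3K-mTOR and sterol synthesis, -1.27 for glycolysis and hypoxia, 2.14 for type I interferon, 2.30 for cytotoxic lymphocytes and NK cells, 1.91 for macrophages, 1.96 for fibroblasts, 1.68 for skeletal muscle and -1.79 for adipocytes. Estimated-correlation adjusted p values of these lists ran from 0.538 to 0.787. With 1 library left out, the interferon value fell to 1.42 (without Keap1-deleted BAP 1), those of NK, macrophages and fibroblasts to 1.56, 1.29 and 1.39 (without Keap1-wildtype untreated 6), and that of muscle ranged from 1.10 (without Keap1-wildtype untreated 2) to 2.74 (without Keap1-deleted BAP 5). Muscle was called in 13 and adipocytes in 16 of those 22 fits, and the other 11 lists in each. Named NRF2 and pentose phosphate genes with a lower effect under BAP were Slc7a11 (-4.28), Gsta2 (-5.08), Abcc4 (-2.04), G6pdx (-1.94) and Taldo1 (-1.72). Lower too were the sterol genes Idi1 (-3.15), Hmgcs1 (-2.12) and Srebf2 (-1.44), the glycolytic gene Pfkp (-1.80), and the basal keratinocyte genes Krt14 (-4.79), Lamb3 (-4.48), Trp63 (-4.07) and Itgb4 (-3.26). Genes of differentiated or stressed keratinocytes with a lower effect were Defb4 (-8.83), Krt13 (-8.37), Sprr3 (-8.28), Sprr2a2 (-8.21), Cldn17 (-8.02), Klk14 (-7.82), Sprr2d (-7.02), Sprr2h (-6.05), Sprr1a (-6.03), Krt6a (-5.56), Il1a (-5.51) and Tgm1 (-5.41).

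Macrophage genes with a higher Keap1 effect under BAP were Siglec1 (10.31), Folr2 (8.87), Mrc1 (6.32), Fcgr1 (5.42), C1qa (5.07) and C1qc (4.84). Interferon genes were Irf7 (5.90), Oas2 (4.39), Zbp1 (4.31) and Stat2 (2.42), and others Nrk (9.06), Pdgfra (4.46) and the NK receptor Klrk1 (3.92). For genes with 0 counts in a group, edgeR adjusted p values of the interaction were 0.0283 for Adcy8, 0.0366 for Cacng2, 0.0299 for Vsig4, 0.0292 for Gria4, 0.0408 for Agtr2 and 0.0477 for Ncr1 (higher), and 0.0452 for Csn1s1 and 0.0341 for Mir7678 (lower). Each called gene named here failed without at least 1 library, and Vsig4 (5.22) and Nrk (2.61) failed also without Keap1-wildtype untreated 6. The total was 1 without Keap1-deleted untreated 1, 2 or 5 and 2 without Keap1-deleted BAP 4.

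Random regrouping of the tumours was compared with the real groups. For the interaction, 1 of 100 splits, the real one, gave as many calls, and the highest of the others gave 1. These splits permuted treatment within genotype, which removed any BAP effect along with the interaction. They argue against a chance assignment of treatment, but do not test the interaction apart from the BAP effects of the genotypes. For the Keap1 effect in BAP tumours 1 of 100 splits gave as many as 7746 (highest other 3930), and for the BAP effect in Keap1-deleted tumours 1 of 100 gave as many as 1172 (highest other 931), which argues against chance for both. For the Keap1 effect in untreated tumours 5 of 100 splits gave as many as 56 and the highest other gave 1255, so chance could not be excluded, and a split with so many calls points to a structure of the samples other than genotype. For the BAP effect in wildtype tumours, with 0 calls by edgeR (2622 genes at an unadjusted p under 0.05, 902 calls by DESeq2 and 0 by limma-voom), all 100 splits gave as many and the highest other gave 3.

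Of 144 group values tested, 11 (7.64%) had a library far from the rest of its group, where chance gives about 1 in 20. Keap1-wildtype untreated 6 was lowest in the basal keratinocyte score (4.95) and highest in the cytotoxic lymphocyte and NK score (1.70). Keap1-deleted BAP 4 was lowest in the basal keratinocyte (2.0), aryl hydrocarbon receptor (2.10) and mast cell (-1.61) scores. Keap1-deleted BAP 1 was highest in the type I interferon (6.27) and oxidative phosphorylation (7.44) scores. Keap1-deleted BAP 5 was lowest in the skeletal muscle score (-0.30), Keap1-deleted untreated 2 highest in the neutrophil score (5.13), Keap1-wildtype BAP 2 lowest in log2 CPM of Nfe2l2 (6.40), and Keap1-deleted untreated 5 lowest in log2 CPM of Trp53 (3.58).

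In Keap1-deleted BAP tumours keratinocyte genes were low and fibroblast and macrophage genes high. A lower share of keratinocyte-derived cells, with the mix of other cells unchanged, would raise markers of other cell types alike. The mean fibroblast and macrophage score was set against that of 6 other cell types (T cells, B cells, neutrophils, adipocytes, endothelium and nerve). It exceeded theirs by 6.18 ± 0.72 (SD, n = 5) in deleted and 3.18 ± 0.51 (SD, n = 6) in wildtype BAP tumours. The difference was 3.0 (exact permutation p = 0.00216), so these scores did not rise alike. However, the neutrophil list shares S100a8 and S100a9 with the list of stress keratins and alarmins. The B cell list holds Sdc1, which epithelial cells also express. Fewer keratinocytes would lower such members, so the difference cannot exclude a lower keratinocyte share with the other mix unchanged. With all 12 other non-epithelial lists in place of those 6, chosen later, the difference was 2.72 (exact permutation p = 0.00216), although skeletal muscle (4.41), NK (2.52) and mast cell (1.98) scores were higher in deleted BAP tumours too. The differentiation score difference of -6.85 was -6.13 with the skeletal muscle score as a covariate and -6.45 with library totals as the only scaling. That argues against muscle taken with the tumour and against scaling as the source of the low differentiation score, and covers that list only. Over all genes the muscle covariate took 7746 calls to 3133, and library totals took the share of higher calls from 50.3% to 73.4%. Fibroblasts and macrophages were chosen because they were high in these libraries, so the values cannot decide on a lower keratinocyte share with another mix of other cells. With the basal keratinocyte score as a covariate, a score that separates these groups, the 7746 calls of this comparison became 0. A change of state in the tumour cells and a fibroblast-rich and macrophage-rich stroma stay open too, and neither was tested.

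NRF2 targets scored 1.64 higher with Keap1 deletion in untreated tumours and 0.10 higher in BAP tumours. Keap1 left intact in the BAP group as a whole is argued against by a log2 fold change of Keap1 of -0.93 there (-0.98 in untreated tumours, edgeR adjusted p = 0.137), although the BAP call is lost without Keap1-deleted BAP 3 or 5 and with library totals (-0.50, adjusted p = 0.235). This does not cover the library labelled Keap1-deleted BAP 2, which held 65.6 CPM of Keap1, within the wildtype range. Counts of whole tumours also take in cells without the Cre. The Keap1 call in BAP tumours was lost, too, when the basal keratinocyte score was a covariate (0 genes called). Because that score separates the BAP groups, the part of cell content in the Keap1 fold change cannot be told. With the basal keratinocyte score as a covariate the interaction of the list was -0.24 (camera adjusted p = 0.229) and the Keap1 effect in BAP tumours 1.66 (adjusted p = 2.29e-15), which is consistent with a lower keratinocyte content of the Keap1-deleted BAP libraries as the source. That score does not overlap between the BAP groups, so the adjustment extrapolates. A lower NRF2 activity in the Keap1-deleted BAP tumours, with Nfe2l2 itself at -1.73, stays open and was not tested.

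Keap1-wildtype untreated 6 lay near the Keap1-deleted BAP tumours, at 162 on the first principal component. It held 78.9 CPM of Keap1, above the highest of the libraries labelled Keap1-deleted (65.6 CPM, with a mean over these libraries of 29.6 ± 15.2 CPM, SD, n = 10). That argues against a Keap1-deleted tumour under a wildtype label. The library at 65.6 CPM is itself within the wildtype range, however, so the Keap1 level alone does not settle a label. It was the highest of its group in 10 of 14 lists of non-epithelial cell types. More surrounding tissue in that sample cannot be told apart from a tumour with more stroma, since the files hold no histology. No biological explanation was tested for this library.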

How the results depend on the processing

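Leaving out 3 libraries together (Keap1-wildtype untreated 6, the library labelled Keap1-deleted BAP 2 and Keap1-deleted BAP 4), titles not ending in R, the Ddx3y covariate, library totals and the settings of list tests other than correlation and fry were chosen after the data were seen. No paired analysis was possible because no label pairs tumours across groups. Where no reason is stated, the cause was not tested.

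The 56 calls of the Keap1 effect in untreated tumours became 915 by the DESeq2 test, 3431 by limma-voom, 36 without the low-count filter, 28 with the R suffix as a covariate, 13 with the muscle covariate, 115 with the basal keratinocyte covariate and 2438 with 3 libraries left out. By edgeR 0 passed with only the groups compared (2379 at an unadjusted p under 0.05) and 0 among titles not ending in R (1817). The 7746 calls of the Keap1 effect in BAP tumours became 3133 with the muscle covariate and 0 with the basal keratinocyte covariate (1084 at an unadjusted p under 0.05), a score that separates these groups. The 0 calls of the BAP effect in wildtype tumours became 902 by DESeq2, 37 with the R suffix and 474 among titles not ending in R. The 1172 calls of the BAP effect in deleted tumours became 2063 by DESeq2, 3791 by limma-voom, 398 without the filter, 352 with only the groups compared, 2 with the basal keratinocyte covariate and 11 among titles not ending in R. The 1333 calls of the interaction became 2914 by DESeq2, 111 without the filter, 3021 with the R suffix, 415 with the muscle covariate, 0 with the basal keratinocyte covariate (1329 at an unadjusted p under 0.05), 689 with 3 libraries left out and 680 among titles not ending in R.

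With 1 library left out, calls ranged from 16 to 2731 in untreated tumours, from 6768 to 7536 in BAP tumours, from 0 to 0 for BAP in wildtype tumours, from 181 to 1597 for BAP in deleted tumours and from 1 to 2309 for the interaction. The NRF2 score difference ranged from 1.47 to 1.93 in untreated tumours (exact permutation p from 0.00476 to 0.0159) and from -0.13 to 0.30 in BAP tumours.

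Of 32 lists, camera called 18, 15, 18, 17 and 13 in the 5 comparisons, and 0 in each with an estimated correlation. By fry, which tests a list without other genes as a reference, 6 were called in untreated tumours, 0 for BAP in wildtype tumours, 11 for BAP in deleted tumours and 5 for the interaction. With the basal keratinocyte covariate 11 were called for BAP in wildtype tumours and 6 for the interaction, none of them among the 13, and with 3 libraries left out 9 for BAP in wildtype and 10 for BAP in deleted tumours.

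With the basal keratinocyte covariate, a score that separates the BAP groups, several directions reversed, not all of them with a call. Differentiation differed by 0.77 and stress keratins by 0.92 with deletion in untreated tumours, where neither was called with all libraries (-0.54 and -0.0277) and differentiation was -1.50 with 3 libraries left out. In BAP tumours differentiation differed by 0.86, interferon by -0.73, partial epithelial-mesenchymal transition by -0.15, NK by -0.11 and MHC class II by -0.0332, and stress keratins by -0.0562 for BAP in wildtype tumours. For BAP in deleted tumours differentiation was 0.48, fibroblasts -1.10, macrophages -0.34, NK -0.52 and interferon -0.86, and for the interaction differentiation was 0.0847 and fibroblasts -0.34. Among the reversed lists that camera did not call were macrophages for BAP in deleted tumours (adjusted p = 0.689) and stress keratins for BAP in wildtype tumours (0.9996). Differentiation (0.469) and fibroblasts (0.611) of the interaction were not called either. The sign reversed for Sprr1a (0.87), Krtdap (1.19), Krt6a (0.57), Krt16 (0.89), Krt6b (0.64), Hk2 (0.0422), Hmox1 (0.46), Ddx58 (-0.16) and Ifit2 (-0.36) with deletion in BAP tumours, Cldn4 (0.35) and Krt17 (0.0725) for BAP in deleted tumours, and Gsta2 (0.88), Krt14 (0.0675), Sprr1a (0.16) and Sprr2h (0.91) for the interaction. None of these genes passed with the covariate (edgeR adjusted p from 0.889 for Gsta2 to 0.999 for Hk2), so no change in the other direction was shown for them. The interferon difference in untreated tumours was 0.14 with 3 libraries left out, and with 1 left out ranged from -0.91 (without Keap1-wildtype untreated 4) to 0.0813 (without Keap1-wildtype untreated 6). That for BAP in deleted tumours ranged from -0.12 (without Keap1-deleted BAP 1) to 0.96 (without Keap1-deleted untreated 4).

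Of named gene results, 158 were weaker with the basal keratinocyte covariate, 101 among titles not ending in R, 78 without the filter and 69 with the muscle covariate, and 2 with DESeq2 size factors. Library totals moved the median log2 fold change of all genes by 0.11, 0.44, -0.18, 0.15 and 0.33 in the 5 comparisons, and limma-voom by 0.10 in untreated tumours and -0.11 for the interaction. The share of calls that were higher went from 50.3% to 73.4% in BAP tumours with library totals, from 35.6% to 62.2% for the interaction, from 73.2% to 88.1% in untreated tumours and from 15.4% to 26.7% for BAP in deleted tumours. By DESeq2 it was 45.1% in untreated tumours and 47.6% for the interaction, by limma-voom 62.5% in untreated and 42.8% for BAP in deleted tumours, and in untreated tumours 83.3% without the filter, 62.2% with the stricter filter, 89.3% with the R suffix, 92.3% with the muscle and 83.5% with the basal keratinocyte covariate. For the interaction it was 24.3% without the filter, 20.5% with the Ddx3y covariate, 53.1% among titles not ending in R and 24.96% with 3 libraries left out, and for BAP in deleted tumours 27.3% with only the groups compared, 36.4% among titles not ending in R and 0% with the basal keratinocyte covariate. With 1 library left out, higher calls ranged from 15 to 1641 and lower from 1 to 1090 in untreated tumours, from 20 to 263 and 161 to 1334 for BAP in deleted tumours, and from 0 to 989 and 1 to 1320 for the interaction.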

Other observations

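The gene families, the relation between scores and the scan of neighbouring genes in this part were chosen after results had been seen, and the scan was redefined after its first output.

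In Keap1-deleted BAP tumours, families of the skin barrier fell, some of them with members that the lists above hold too, such as Sprr3 and Sprr1a. Among 33 families, all 10 measured kallikreins, the proteases that loosen the outer epidermis, fell (median log2 fold change -5.72), as did 15 of 16 Sprr genes (-7.11), 16 of 21 late cornified envelope genes (-4.06) and 7 of 9 desmosomal cadherins (-5.04). Families were taken by gene symbol, so some hold pseudogenes or related genes. Of 16 complement genes 12 rose and 0 fell (4.40), of 11 toll-like receptors 9 rose (3.17) and of 11 Fc gamma and Siglec receptors 8 rose (4.11). Of 11 immunoglobulin constant genes, with the joining chain gene Jchain counted among them, 8 rose and 1 fell (4.47). Of 43 collagens 19 rose and 2 fell (1.67), and of 22 ADAMTS and ADAMTS-like genes 12 rose and 2 fell (2.65). Adjusted p values of these 10 families with an estimated correlation were 0.384 each. Of 16 glutamate receptor genes 8 rose and 2 fell, among them Gria4, Grik2 and Grin3a, and of 16 Wnt ligands 6 fell and 1 rose (camera adjusted p = 0.0898 and 0.0577). In untreated tumours 4 of 24 glutathione transferase genes, the pseudogene Gstp-ps among them, rose with deletion and 0 fell (median 1.54). The camera adjusted p was 1.24e-06 with the preset and 0.230 with an estimated correlation. The shift of all genes with library totals, 0.44 and 0.11 in these comparisons, is smaller than each of these medians.

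NRF2 target and basal keratinocyte scores rose and fell together across the 10 tumours labelled Keap1-deleted, with Pearson r 0.887 (permutation p = 4.5e-04, adjusted p = 9e-04 over 2 relations) and Spearman rho 0.758 (permutation p = 0.0154). The value of r was 0.834 without the tumours farthest from the median, Keap1-deleted BAP 4 and Keap1-deleted untreated 5, 0.888 without the library labelled Keap1-deleted BAP 2 and 0.768 after removing group means. Across the 12 wildtype tumours r was 0.696 (permutation p = 0.00596), rho 0.657 (permutation p = 0.0242), r without the 2 farthest tumours 0.551 and r after removing group means 0.666. A candidate explanation is that NRF2 target level follows the keratinocyte content of a sample, a hypothesis found and tested on the same libraries.

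Runs of neighbouring genes were together highest or lowest in 1 library. Over 13548 genes in genomic order, 12 runs held windows of 9 genes with at least 8 at an extreme in 1 library, while 17 of 1000 shuffles of the gene order gave any such window, with at most 8 of 9. In Keap1-deleted BAP 5 the run from St3gal4 to Hyls1 on chromosome 9 was highest in 9 of 10 genes, at a median of 25.8 times the median library. On the same chromosome and in the same library, looked up after Cfap300 and Cep126 had been named and not 1 of those runs, 10 of 15 genes from Dync2h1 to Trpc6 were highest, with Yap1 at 2562 CPM against 184 CPM in the next library and Birc2 at 786 CPM against 72.5 CPM. In Keap1-wildtype untreated 4 the run from Sike1 to Bcl2l15 on chromosome 3, which holds Nras (877 CPM against 364 CPM in the next library), was highest in 11 of 12 genes at a median of 7.39 times, and that from Wdr3 to Ptgfrn in 8 of 9 at 4.70 times. Further runs were Polr3c to Prkab2 on chromosome 3 in Keap1-wildtype BAP 6 (3.95 times), Wdr70 to Lmbrd2 on chromosome 15, with Skp2, in Keap1-wildtype untreated 5 (3.58 times), Armh4 to Rnase6 on chromosome 14 in Keap1-wildtype untreated 6 (2.98 times), and Ankle2 to Hscb on chromosome 5, lowest in Keap1-deleted untreated 3. The others lay in keratinocyte gene clusters or were lowest in Keap1-deleted BAP 4. The first form of the scan gave 713 runs, of which the 12 longest lay on chromosome 3. A copy number change may lie behind runs such as those with Yap1 or Nras, but DNA was not measured, and shared regulation of neighbours gives runs too.

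Ddx3y, a Y-linked gene, reached 1 CPM in 4 of 6 Keap1-wildtype untreated, 2 of 6 Keap1-wildtype BAP, 3 of 5 Keap1-deleted untreated and 3 of 5 Keap1-deleted BAP tumours. With its level as a covariate 47, 7223, 0, 1179 and 898 genes were called by edgeR in the 5 comparisons, where for the BAP effect in wildtype tumours 1911 had an unadjusted p under 0.05, DESeq2 called 902 and limma-voom 0 without that covariate.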
